A study of Homo sapiens with 4 samples.

How the data were processed

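A-seq libraries of HEK293 cells were compared between 4 groups with 1 library each: no siRNA, control siRNA, siRNA against CstF-64 and siRNA against CF Im 68. Per the labels' protocols, poly(A) RNA was selected on oligo-dT beads and partly digested with RNase I. Reverse transcription started from an oligo-dT primer with an anchor base at the junction of transcript and poly(A) tail. A read 3′ end therefore marks a cleavage and polyadenylation position. Oligo-dT primers can also start within A-rich stretches of a transcript, and reads of such internal priming were not separated from true 3′ ends here.

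The deposited values were read counts per single-nucleotide 3′ end position and strand, as the authors left them, without normalization. The coordinates were on hg19 (GRCh37), per the submitters' processing notes, and are given 1-based. The aligner, the handling of reads with several matches and the handling of PCR copies were not given in the sources used here. The authors' running numbers of the positions had gaps that left out 12.2% of the numbers in the no siRNA library, 10.8% after control siRNA, 10.2% after CstF-64 siRNA and 11.3% after CF Im 68 siRNA. Positions had therefore been removed after numbering, by a rule not given in the sources used here. Any site removed in that step has no counts here. No molecular identifiers were given in the labels, so that copies of 1 fragment count as several reads, and the exact intervals of shares and ratios cover counting error only.

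Read totals were 15806975 without siRNA, 13443454 after control siRNA, 7343112 after CstF-64 siRNA and 12792623 after CF Im 68 siRNA. Positions with a single read made up 62.7%, 66.3%, 65.5% and 61.6% of the 689381, 771977, 448689 and 728173 positions, in the same order. The 1749181 positions of all libraries were clustered per strand: the position with the most reads over the 4 libraries took all positions within 25 nt, and this was repeated until none were left. Of the 1156237 clusters, those with a mean of at least 1 RPM (reads scaled by the library total in the usual way) on chromosomes 1 to 22 and X were kept as sites. Chromosome Y was left out. The 33723 sites held 94.2% of reads without siRNA, 92.3% after control siRNA, 93.0% after CstF-64 siRNA and 89.5% after CF Im 68 siRNA.

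The design called for terminal exons. No annotation of hg19 was used here, and the fallback fixed with it was applied: the most used site took all sites of its strand within 10 kb, and each such group is called a locus. A locus can therefore hold more than 1 gene. Sites with at least 5% of the mean locus reads over all libraries were kept. The depleted libraries took part in this choice, so a site used mainly after a depletion could enter by its rise. The 2 most used of these formed a pair, and loci with at least 50 pair reads in every library were tested. The proximal share is the percentage of pair reads at the site nearer the 5′ side. At 50 reads, a share of 50% has an exact Clopper-Pearson 95% interval of 35.5 to 64.5%, and the median pair had 402 reads without siRNA, 366 after control siRNA and 384 after CF Im 68 siRNA, with fewer after CstF-64 siRNA.

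Pair reads were compared between libraries with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment over tested loci. With 1 library per group, this test compares 2 libraries and not conditions. A locus was counted as moved when the adjusted p against control siRNA was below 0.05, the proximal share differed from control siRNA by at least 10 percentage points, and it differed from the no siRNA library by at least 10 points in the same direction. Comparisons of 2 libraries alone used the first 2 of these conditions. Medians over loci carry 95% order-statistic intervals, which treat loci as independent. The mean end distance of a locus was the read-weighted mean distance of its sites from its most 5′ site. Locus totals were compared as log2 ratios of RPM plus a pseudocount of 1, in loci with at least 50 reads over the libraries, without a test.

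The rule was tested on simulated libraries. The 4793 tested loci were given the pooled control shares, the real read numbers, and known changes at 200 loci. These changes were rises in proximal share at loci with low to middle control shares. Falls, changes at loci with high shares, and the choice of sites were not simulated. Libraries were drawn with and without the extra spread found between the control libraries. This spread includes any effect of the control siRNA treatment. For the CF Im 68 comparison with that spread, 54% of changes of 15 points, 66% of 20 points, 96% of 30 points and 98% of 40 points were recovered, 50 loci per size. For the CstF-64 comparison the same sizes gave 62%, 66%, 92% and 100%.

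The loci named in the text followed a rule fixed before the data were examined, as were the groups, the tests and most of the other settings tried. For each depletion it took the 12 moved loci with the largest rise and the 12 with the largest fall in proximal share, ranked by the smaller of the changes against the 2 controls. For locus totals it took the 10 largest rises and the 10 largest falls per depletion, with the same sign against both controls, at least 20 RPM in 1 library and a log2 ratio between the controls within 1. The rule also named the targeted genes, members of gene lists and genes with intronic sites. These need an annotation of the build and were not analysed here, and loci are given by position. The gene tables used here hold another build, so no gene name was assigned to a position. For the same reason, the levels of the targeted transcripts were not analysed here, and the labels of the depletions were not checked from the counts.

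Settings fixed in advance changed the cluster radius, the read minimum, the size of the change, the choice of sites, the depth, the control library, the scaling of locus totals, their pseudocount and their read minimum. Further settings were added after seeing the data: a locus window of 2 kb, leaving out sites with at least 99% of their reads in 1 library, leaving out the most read position of each site, and applying the rule to a control library in place of a depleted one. Intended but not run were the counting of distinct alignments, the removal of sites next to A stretches, the extension of terminal exons and all steps on introns, targeted genes and sequence around sites, since the deposited positions carry no alignments and no genome or annotation of the build was used here. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors and DESeq2 1.42.0 for size factors.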

Results

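Polyadenylated RNA 3′ ends were counted by A-seq in HEK293 cells, a line derived from human embryonic kidney. The 4 libraries, 1 per group, came from cells without siRNA, with a control siRNA, with an siRNA against CstF-64 and with an siRNA against CF Im 68. The siRNA-treated cells were harvested after 3 days. CF Im 68 is a subunit of cleavage factor I, which binds UGUA elements upstream of poly(A) sites. CstF-64 is the RNA-binding subunit of the cleavage stimulation factor, which binds U- and GU-rich elements downstream of the cleavage position. The depletions addressed how these factors bear on the choice between alternative poly(A) sites and on 3′ UTR length. The libraries held 15806975 reads without siRNA, 13443454 with control siRNA, 7343112 with CstF-64 siRNA and 12792623 with CF Im 68 siRNA. No group had a replicate, so the spread between cultures is unknown. The difference between the 2 control libraries is given as background. These were treated differently, with control siRNA or with no siRNA, so their difference also includes any effect of that treatment.

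The reads defined 33723 nuclear 3′ end sites in 18156 loci on hg19, from which internal priming was not separated. In 11595 loci a single site held at least 5% of the reads, 6561 loci had at least 2 such sites and 2731 had at least 3. Proximal and distal use could be compared in 4793 loci, with a median distance between the paired sites of 1115 nt and quartiles of 296 and 2746 nt. The median proximal share was 42.0% without siRNA, 41.7% after control siRNA, 43.9% after CstF-64 siRNA and 52.5% after CF Im 68 siRNA.

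Depletion of CF Im 68 came with a broad move to proximal poly(A) sites. Of the 4793 loci, 1161 (24.2%) moved to the proximal site and 126 (2.63%) to the distal site against both control libraries, so that 90.2% of the 1287 moved loci went to the proximal site. This balance depended in part on the starting share, since a share near 0 or 100% has little room to fall or rise. In loci with 25 to 50% proximal use in the controls, 368 moved to the proximal and 27 to the distal site, and with 50 to 75% the counts were 217 and 45. Below 25% they were 551 and 5, and above 75% they were 25 and 49. Sites and pairs were chosen on the mean of all libraries, including the depleted ones. A site that rose after a depletion could thus enter the tested set by that rise. The counts, percentages and medians therefore describe the chosen pairs and not all loci. The median change in proximal share was 4.84 percentage points over control siRNA (95% order-statistic interval 4.55 to 5.14) and 5.23 points over no siRNA (4.81 to 5.57). The share was larger than after control siRNA at 71.6% of loci and larger than without siRNA at 68.0%. The control libraries differed from each other with no such bias. In that comparison 510 loci passed the 2-library test toward the proximal and 531 toward the distal site, with a median difference of 0.217 points (0 to 0.461) and a median absolute difference of 5.01 points. Under the same 2-library test, CF Im 68 siRNA gave 1466 proximal and 207 distal loci against control siRNA and 1676 and 426 against no siRNA. In simulated libraries with no change at 4593 loci but the spread found between the controls, the rule against both controls called 175 proximal and 171 distal loci. With the no siRNA library in place of the depleted one, against control and CstF-64 siRNA, the same rule gave 373 proximal and 385 distal loci, and with the control siRNA library, against no and CstF-64 siRNA, 62 and 87. The 1161 proximal calls were above all of these numbers and the 126 distal calls were not.

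**Figure D1:**
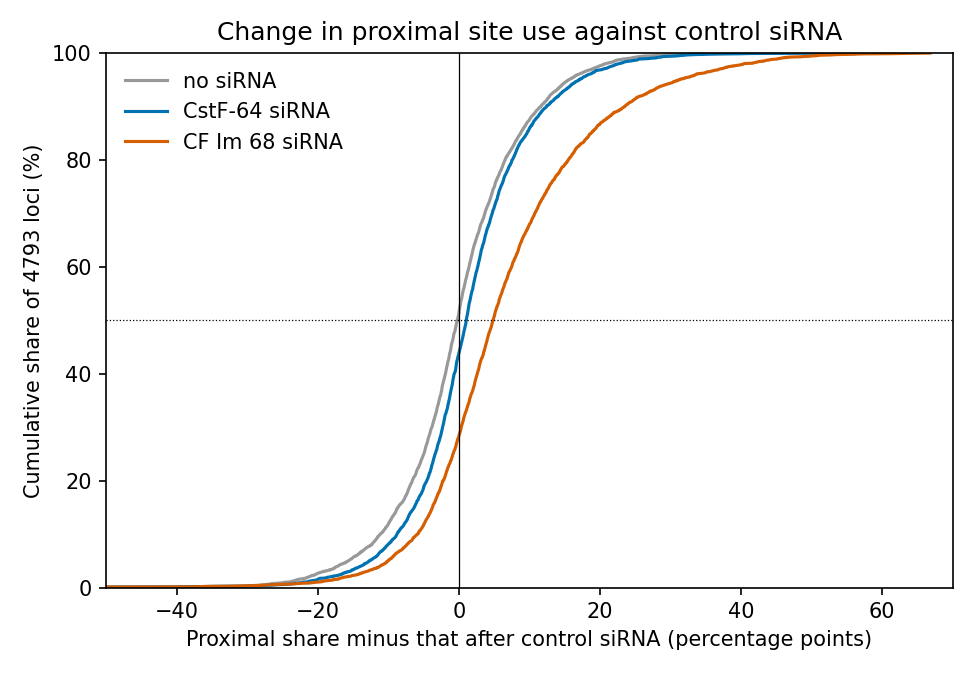
Cumulative share of the 4793 tested loci (%) against the proximal share minus that after control siRNA (percentage points), 1 line per library. The CF Im 68 line lies to the right of the others, with a median of 4.84 points, against 1.04 points for CstF-64 siRNA.

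The 12 loci with the largest moves to the proximal site after CF Im 68 siRNA had proximal shares of 2.65 to 35.4% in the control libraries and changes of 52.8 to 62.0 points, over distances of 715 to 4796 nt. On the plus strand of chromosome 5, the site at 109203136 had 20.8% of the reads of its pair with 109205326 without siRNA (95% exact Clopper-Pearson interval 13.2 to 30.3) and 16% after control siRNA (10.4 to 23). It had 82.8% after CF Im 68 siRNA (79.2 to 86.0, 506 reads) and 19.7% after CstF-64 siRNA (11.2 to 30.9). On chromosome 11, plus strand, the share of the site at 13750435 over that at 13753042 was 16.1% and 12% in the controls, 12.2% after CstF-64 siRNA and 75.8% after CF Im 68 siRNA (72.5 to 79.0). The pair at 20451050 and 20448501 on the minus strand of chromosome 2 went from 7.84% and 5.90% to 67.3% (63.8 to 70.7). At 92028550 and 92030692 on the plus strand of chromosome 7, the share was 17.6% and 9.86% in the controls and 76.5% after CF Im 68 siRNA (72.7 to 80.1). The pair at 60339253 and 60342041 on the plus strand of chromosome 1 had 5.51% and 13.2% in the controls and 69.5% after CF Im 68 siRNA (64.5 to 74.1). At 55497549 and 55495167 on the minus strand of chromosome 15 the share was high after either depletion, with 89.1% after CF Im 68 siRNA (85.7 to 91.9) and 75.3% after CstF-64 siRNA (64.2 to 84.4), against 32.4% and 35.4% in the controls.

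Moves to the distal site after CF Im 68 siRNA covered 30.1 to 92.6 points among the 12 largest. On the plus strand of chromosome 1, the site at 66101111 fell from 84.3% without siRNA and 84.4% after control siRNA to 16% (12 to 20.8) of its pair with 66102008. At 102551279 on the minus strand of chromosome 14, paired with 102547931, the share was 96.2% and 96.0% in the controls, 89.6% after CstF-64 siRNA and 44.2% after CF Im 68 siRNA (42.3 to 46.1, 2681 reads). The pair at 50265742 and 50269218 on the plus strand of chromosome 16 had 99.5% and 97.5% in the controls and 48.1% after CF Im 68 siRNA (42.0 to 54.3). The largest of these changes, at 151530457 and 151532893 on the plus strand of chromosome 1, rested on a distal site made of 1 position with at least 99% of its reads in the CF Im 68 library. There the proximal share was 100% in the other libraries, with lower limits of 96.3 to 98.0%, and 7.44% after CF Im 68 siRNA.

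**Figure D2:**
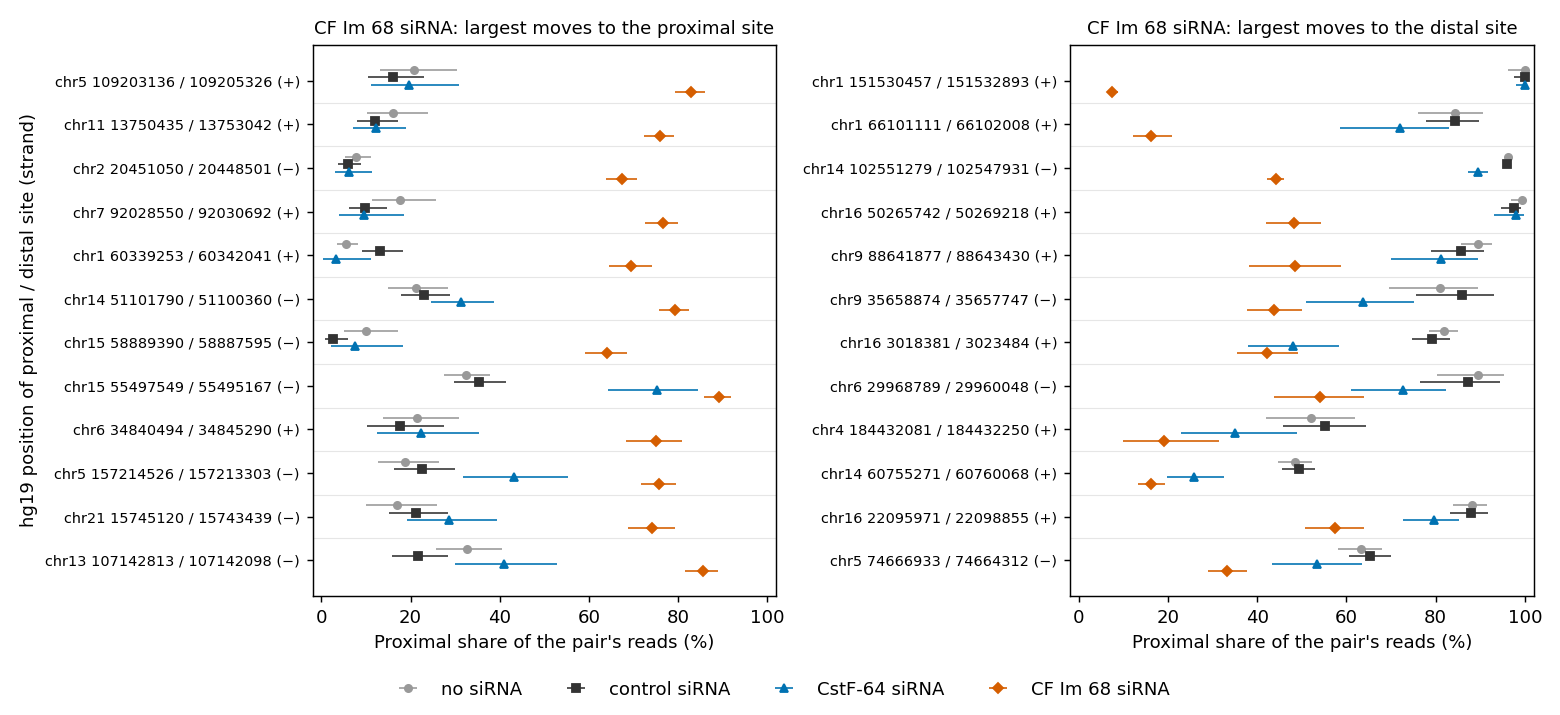
Proximal share of the pair's reads (%, x axis) at the 12 loci with the largest moves to the proximal site and the 12 with the largest moves to the distal site after CF Im 68 siRNA, by hg19 position, with points for the 4 libraries and bars for 95% exact Clopper-Pearson intervals. After CF Im 68 siRNA the proximal loci lie between 63.95 and 89.1% and the distal loci between 7.44 and 57.3%.

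The move after CF Im 68 siRNA was most frequent at sites 1001 to 2000 nt apart, where 326 of 884 loci (36.9%) moved to the proximal site and 20 (2.26%) to the distal site. At distances of 26 to 100 nt, 34 of 535 loci (6.36%) moved to the proximal site. Positions were clustered within 25 nt only, so pairs of this class can also be parts of a single broad site. The percentages were 12.4% at 101 to 200 nt, 17.7% at 201 to 500 nt, 27.8% at 501 to 1000 nt, 32.8% at 2001 to 5000 nt and 17.7% at 5001 to 10000 nt. Moves to the distal site were also more frequent at long distances, with 0.935% at 26 to 100 nt, 3.93% at 2001 to 5000 nt and 5.26% at 5001 to 10000 nt.

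**Figure D3:**
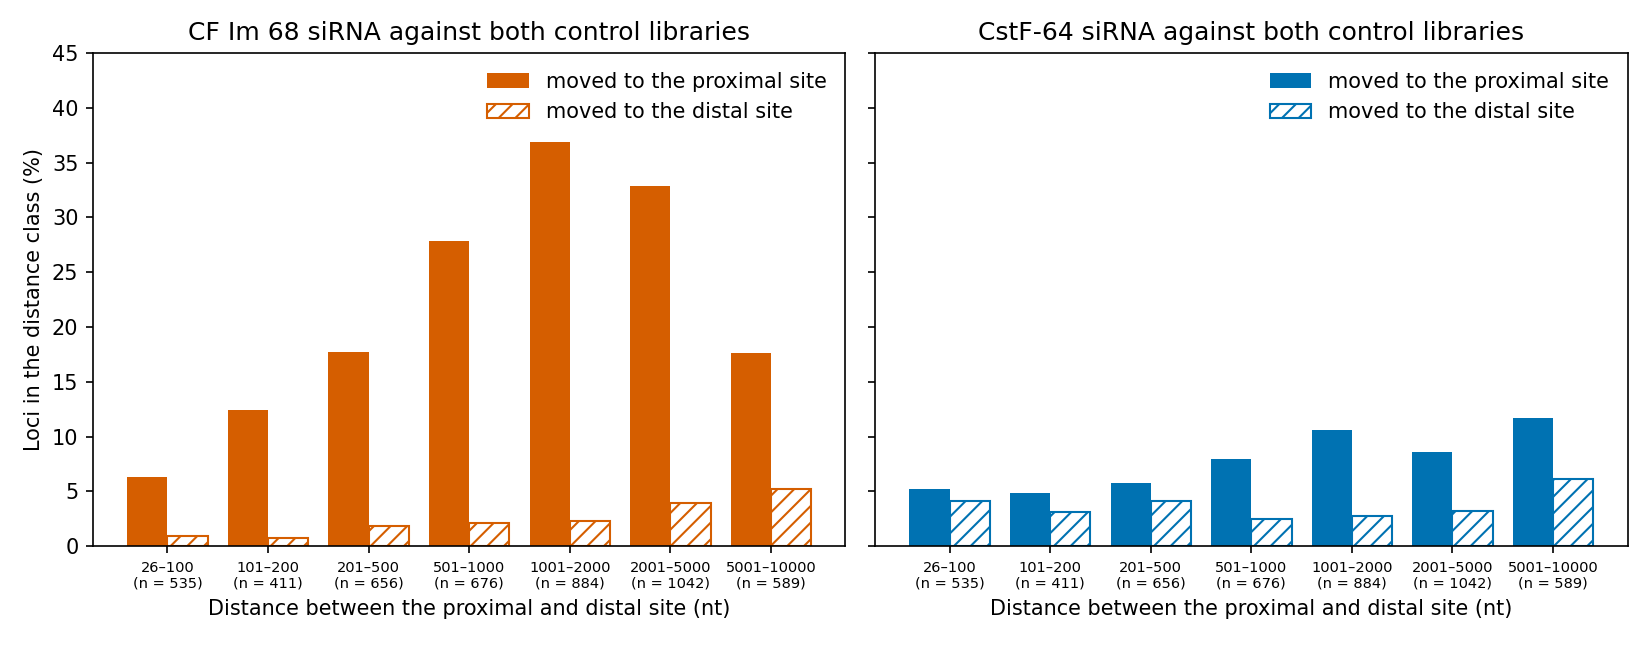
Percentage of tested loci in each class of distance between the paired sites (nt) that moved to the proximal site (filled bars) or to the distal site (hatched bars) against both control libraries, for CF Im 68 siRNA (left) and CstF-64 siRNA (right), with the number of loci under each class. The proximal percentage after CF Im 68 siRNA rises to 36.9% at 1001 to 2000 nt, and after CstF-64 siRNA it lies between 4.87 and 11.7%.

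In loci with several sites, reads went to the most 5′ sites after CF Im 68 siRNA. In the 1426 loci with 3 sites and enough reads, the mean share of the most 5′ site was 29.2% without siRNA, 29.1% after control siRNA, 30.2% after CstF-64 siRNA and 38.0% after CF Im 68 siRNA. The mean share of the most 3′ site was 38.1%, 38.0%, 36.3% and 30.3% in the same order. In the 245 loci with 5 sites, the most 5′ site had 15.8% in each control library, 15.7% after CstF-64 siRNA and 26.1% after CF Im 68 siRNA. The next site rose as well, from 17.5% and 18.0% in the controls to 22.2%.

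**Figure D4:**
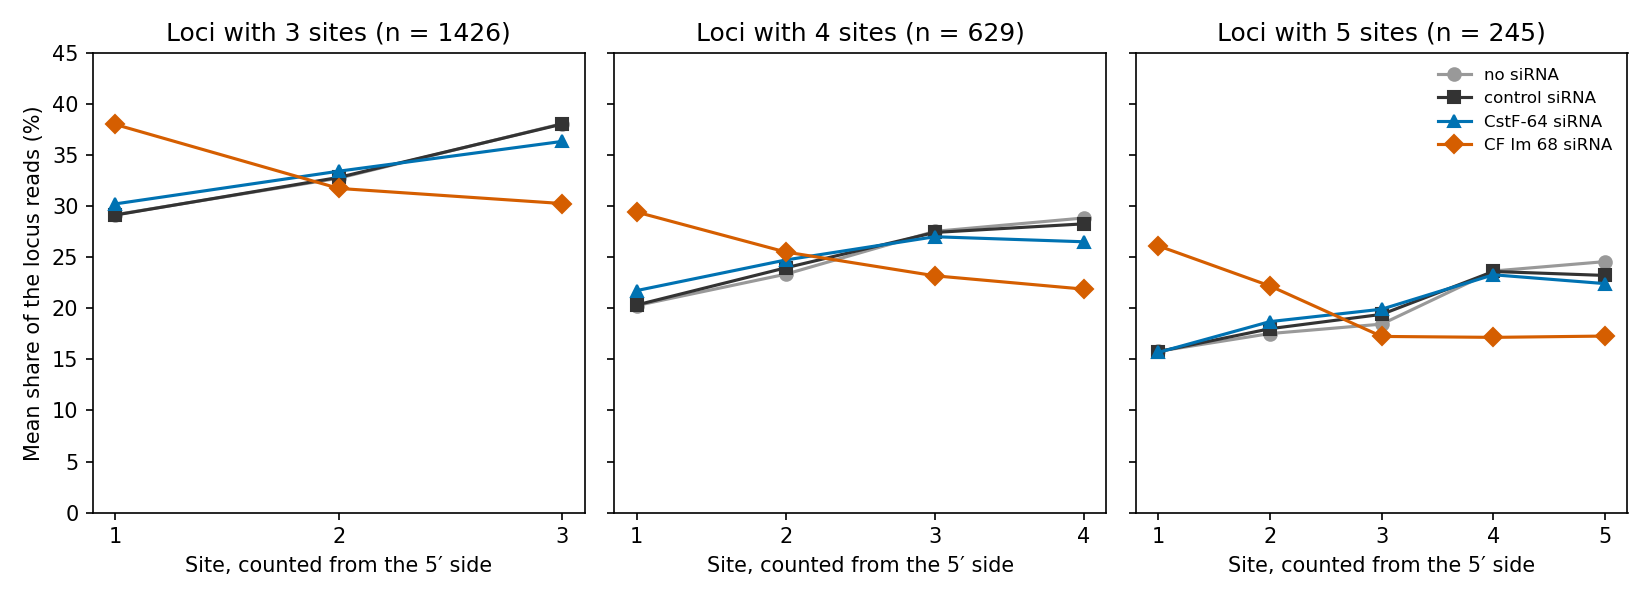
Mean share of the locus reads (%) at each site, counted from the 5′ side, in loci with 3, 4 and 5 sites, 1 line per library. In loci with 5 sites the CF Im 68 library falls from 26.1% at the most 5′ site to 17.3% at the most 3′ site, while the control libraries rise from 15.8% to 24.6% and 23.2%.

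Depletion of CstF-64 came with a smaller change in site use. Against both controls, 393 loci moved to the proximal site (8.20%) and 172 to the distal site (3.59%), so that 69.6% of 565 moved loci went to the proximal site. This balance also depended on the starting share. With 25 to 50% proximal use in the controls, 146 loci moved to the proximal and 57 to the distal site, and with 50 to 75% the counts were 106 and 58. Below 25% they were 127 and 8, and above 75% they were 14 and 49. The choice of sites on the mean of all libraries bears on these counts as well. The median change was 1.04 points over control siRNA (0.841 to 1.24) and 1.18 points over no siRNA (0.906 to 1.53). Simulated libraries of this depth with no change at 4593 loci and the spread between the controls gave 189 proximal and 195 distal calls. With the no siRNA library in place of the depleted one, the rule gave 373 proximal and 385 distal loci, 758 in all, and with the control siRNA library 62 and 87. These rotated comparisons use the CstF-64 library as a reference. The 393 proximal calls were above the simulated number and that of the control siRNA library, and close to that of the no siRNA library, whose moves were 49.2% proximal. The 172 distal calls were below the simulated number and that of the no siRNA library, and above that of the control siRNA library. With the no siRNA library as the single control, the counts were 911 proximal and 642 distal, and with control siRNA alone 510 and 253. With all libraries thinned to the depth of the CstF-64 library, the smallest, 330 loci moved to the proximal and 150 to the distal site after CstF-64 siRNA, against 987 and 104 after CF Im 68 siRNA.

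The 12 largest moves to the proximal site after CstF-64 siRNA spanned 32.7 to 55.9 points. At 128728690 and 128729654 on the plus strand of chromosome 9, the proximal share was 33.1% without siRNA, 31.9% after control siRNA, 75.7% after CstF-64 siRNA (66.8 to 83.2) and 79.1% after CF Im 68 siRNA (75.3 to 82.6). On the plus strand of chromosome 13, the site at 27829666 had 4.71% and 8.18% of its pair with 27830717 in the controls and 49.2% after CstF-64 siRNA (36.1 to 62.3, 61 reads). The pair at 16860093 and 16861345 on chromosome X, plus strand, had 11.5% and 12.3% in the controls, 51.6% after CstF-64 siRNA (38.7 to 64.2) and 52.1% after CF Im 68 siRNA. At other loci the share after CstF-64 siRNA exceeded that after CF Im 68 siRNA. The pair at 113214166 and 113214235 on the plus strand of chromosome 1, 69 nt apart, had 13.5% and 27.6% in the controls, 34.9% after CF Im 68 siRNA and 75.7% after CstF-64 siRNA (64 to 85.2). At 67706961 and 67708399 on the plus strand of chromosome 12, the share was 39.0% and 47.8% in the controls, 62.2% after CF Im 68 siRNA and 80.8% after CstF-64 siRNA (76.8 to 84.4).

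Toward the distal site, the pair at 54678664 and 54679033 on the plus strand of chromosome 12 had 71.6% and 67.8% proximal use in the controls, 71.3% after CF Im 68 siRNA and 16% after CstF-64 siRNA (14.5 to 17.6, 2228 reads). At 24686072 and 24683162 on the minus strand of chromosome 14, the share was 80.2% and 67.3% in the controls, 74.6% after CF Im 68 siRNA and 35.7% after CstF-64 siRNA (32.9 to 38.6). The pair at 3018381 and 3023484 on the plus strand of chromosome 16 fell after either depletion, from 81.9% and 79.1% in the controls to 48.0% after CstF-64 siRNA (37.9 to 58.2) and 42.2% after CF Im 68 siRNA (35.4 to 49.2). Among the 12 largest moves in each direction, 1 to the proximal and 2 to the distal site rested on a site with at least 99% of its reads in 1 library. These lay on the plus strand at 170172891 on chromosome 6 (proximal), and at 65501227 on chromosome 2 and 10697891 on chromosome 1 (distal).

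**Figure D5:**
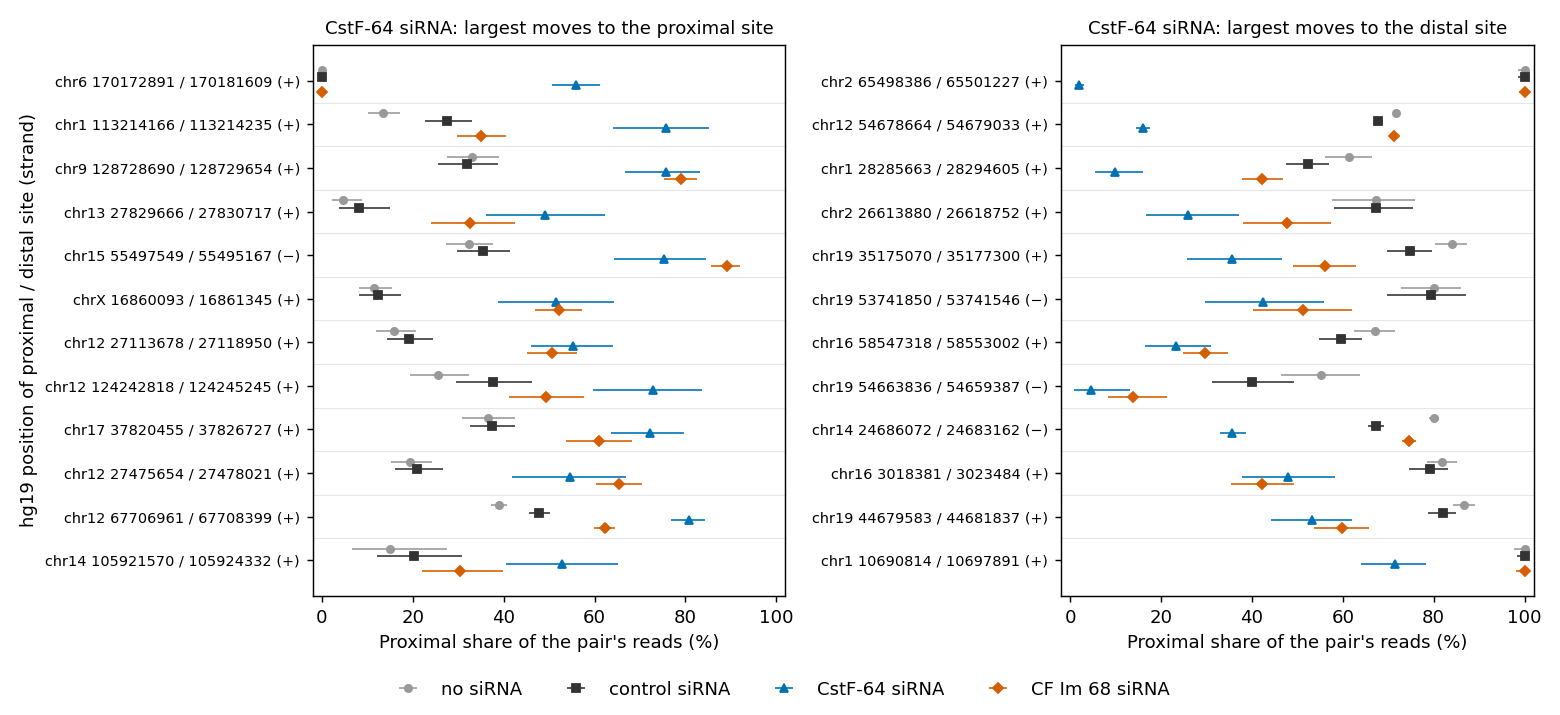
Proximal share of the pair's reads (%, x axis) at the 12 loci with the largest moves to the proximal site and the 12 with the largest moves to the distal site after CstF-64 siRNA, by hg19 position, with points for the 4 libraries and bars for 95% exact Clopper-Pearson intervals. After CstF-64 siRNA the proximal loci lie between 49.2 and 80.8% and the distal loci between 1.97 and 71.5%.

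Compared directly, the CF Im 68 library used proximal sites more than the CstF-64 library. By the 2-library test 1195 loci had a larger and 242 a smaller proximal share after CF Im 68 siRNA, with a median difference of 3.69 points (3.42 to 3.98). The lists of changed loci overlapped more than independent lists would. To keep the controls apart, CF Im 68 siRNA was set against control siRNA and CstF-64 siRNA against no siRNA. Then 415 loci had a larger proximal share in both comparisons, against 279 for independent lists, and 67 a smaller one, against 27.7. Opposite changes were found at 142 loci with CF Im 68 proximal, against 196, and at 22 with CF Im 68 distal, against 39.3. With the controls exchanged, 335 loci were proximal in both, against 178.3, and 89 were distal in both, against 22.5. Pearson's r of the changes across loci was 0.193 and 0.355 in these pairings, and Spearman's rho 0.201 and 0.346. Loci are not independent replicates. The counts for independent lists take no account of the starting share, which went with the direction of moves after either depletion. The excess overlap therefore does not by itself show a shared effect.

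The same changes shortened the mean distance to the 3′ end. In 4984 loci with at least 2 sites and at least 50 reads in every library, the read-weighted mean distance from the most 5′ site fell by a median of 56.8 nt after CF Im 68 siRNA against control siRNA (interval −62.8 to −49.99 nt), and fell by 60.2 nt against no siRNA. It was shorter by at least 200 nt in 1532 loci and longer by as much in 389. The mean over loci was 1281 nt after CF Im 68 siRNA, 1410 nt after CstF-64 siRNA, 1451 nt after control siRNA and 1463 nt without siRNA. After CstF-64 siRNA the median fell by 5.60 nt against control siRNA (−7.22 to −4.21 nt), with 785 loci shorter and 500 longer by at least 200 nt. Control siRNA against no siRNA gave a median of −0.692 nt (−1.53 to 0.0425), with 677 loci shorter and 560 longer.

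Locus totals, which follow transcript abundance, differed as well, with more loci higher after CF Im 68 siRNA and more lower after CstF-64 siRNA. Of 17877 loci, 897 were at least 2-fold higher after CF Im 68 siRNA than in both controls and 332 at least 2-fold lower. After CstF-64 siRNA, 325 were higher and 1092 lower. With the no siRNA library in place of a depleted one, against control and CstF-64 siRNA, the counts were 269 higher and 411 lower, and with the control siRNA library, against no and CstF-64 siRNA, 266 and 23. The balance after CstF-64 siRNA depended on the scaling: 22.9% of its changed loci were higher by total reads, 37.0% with TMM factors (496 higher, 844 lower) and 40.1% with DESeq2 size factors (500 higher, 746 lower). By total reads, the median log2 ratio of CstF-64 to control siRNA was −0.19, and with TMM factors it was −0.01.

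The 10 largest falls after CF Im 68 siRNA included the locus at 5863900 on the minus strand of chromosome 12, with 50.3 RPM without siRNA, 51.1 RPM after control siRNA, 136 RPM after CstF-64 siRNA and 0.156 RPM (2 reads) after CF Im 68 siRNA. The locus at 106956454 on the minus strand of chromosome X had 841 and 570 RPM in the controls, 200 RPM after CstF-64 siRNA and 176 RPM after CF Im 68 siRNA. On the minus strand of chromosome 5, the locus at 172744071 had 170 and 149 RPM in the controls, 58.3 RPM after CstF-64 siRNA and 42.8 RPM after CF Im 68 siRNA. After CstF-64 siRNA, the locus at 24286549 on the plus strand of chromosome 2 fell to 15.7 RPM, from 116 and 135 RPM in the controls, and had 51.9 RPM after CF Im 68 siRNA. The locus at 30055457 on the plus strand of chromosome 19 had 35.4 and 21.4 RPM in the controls, 1.09 RPM (8 reads) after CstF-64 siRNA and 4.53 RPM after CF Im 68 siRNA. At 151995873 on the minus strand of chromosome X, 43.6 and 56.8 RPM in the controls compared with 6.95 RPM after CstF-64 siRNA and 65.2 RPM after CF Im 68 siRNA. The 10 largest rises of each depletion all lay at sites of 1 position with at least 99% of their reads in that library. An example is the locus at 582754 on the plus strand of chromosome 17, with 190 RPM (2433 reads) after CF Im 68 siRNA and 0 reads in the other libraries. With 3 reads taken as the limit, 0 reads allow up to 0.190 RPM without siRNA, 0.223 RPM after control siRNA and 0.409 RPM after CstF-64 siRNA. These limits do not hold where a position was removed after numbering. Without sites that had at least 99% of their reads in 1 library, 709 loci were higher after CF Im 68 siRNA and 210 after CstF-64 siRNA.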

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

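Among the tests below, those on neighbouring genes and on the yield of nuclear mRNA were chosen after the results were seen, and leaving out the most read positions was an added setting.

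The depletions differed from each other in site use. In the direct comparison of their libraries by Fisher's exact test, 1195 loci had a larger and 242 a smaller proximal share after CF Im 68 siRNA than after CstF-64 siRNA, which drew attention as a difference between groups. The excess of proximal moves after CF Im 68 siRNA was weighed against technical explanations. With all libraries thinned to the smallest, 90.5% of moved loci still moved to the proximal site. Random thinning leaves the expected shares as they were, so this balance could hardly have changed and decides nothing on depth. With the most read position of each site left out, 89.7% of moved loci moved to the proximal site, in 2542 tested loci. The median change fell from 4.84 to 2.99 points. This argues against amplified fragments at those positions as the whole cause, but copies at other positions stay in. Pairs at most 500 nt apart were taken as mostly too close for separate genes, which was not checked against an annotation. Of the moved ones, 91.0% moved to the proximal site, so on this assumption different changes of neighbouring genes are unlikely to account for them. Of moved pairs over 5 kb apart 77.0% did, between the bounds set for either outcome, so neighbouring genes stay open for them. Pairs in between hold most of the moves, and no bounds were set for them. Their counts were 188, 326 and 342 proximal against 14, 20 and 41 distal at 501 to 1000, 1001 to 2000 and 2001 to 5000 nt. Changes of neighbouring genes were taken to go equally often both ways, and these did not. This argues against neighbouring genes as the whole cause of the excess there, though single pairs can still join separate genes. An effect of the CF Im 68 depletion itself is a hypothesis that these libraries cannot test, since with 1 library per group a difference of that culture unrelated to the depletion stays open.

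Mitochondrial reads, which count in the library totals but whose sites the comparisons above leave out, made up 3.75% of reads after CF Im 68 siRNA (exact interval 3.74 to 3.76%) and 1.79% after CstF-64 siRNA, above 1.53% after control siRNA and 1.17% without siRNA. The rise was uneven after either depletion, and after CstF-64 siRNA the summed reads outside the 4 largest sites were below both controls on either strand. After CF Im 68 siRNA, plus-strand reads outside the 4 largest mitochondrial sites were at 1.05 times their control siRNA level (1.03 to 1.07) and 1.56 times their no siRNA level, and minus-strand reads outside these sites at 1.65 times (1.63 to 1.68) and 1.93 times, while the 4 largest sites together were at 2.97 and 3.88 times. These unequal ratios argue against a lower yield of nuclear mRNA as the whole cause, since that would raise all mitochondrial sites by one factor. With the most read position of each site left out, the share was 2.30 times that of control siRNA, so amplification of single fragments at those positions is unlikely to be the whole cause. An effect of the depletion on mitochondrial transcripts or on their poly(A) tails may remain, as may a difference of this culture, and neither was tested.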

How the results depend on the processing

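The settings that leave out the most read position or the sites of 1 library, and the 2 kb window, were chosen after seeing the data. Over 164 values under other settings no median changed sign, and 104 values stayed within 1.5 times (counts) or inside the interval (medians and shares). Depth limits how many loci can be tested, and the CstF-64 library had the fewest reads.

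With at least 200 reads per pair, 2166 loci were tested. CF Im 68 siRNA gave 465 proximal and 39 distal loci with a median of 4.16 points, CstF-64 siRNA 185 and 83, control against no siRNA 218 and 210, and CF Im 68 against CstF-64 siRNA 492 and 100 with a median of 3.00 points. The median change of the mean end distance after CF Im 68 siRNA was −42.1 nt. Without the most read position of each site, 2542 loci were tested. The counts were 443 and 51 (median 2.99 points) for CF Im 68 siRNA, 128 and 72 (median 0.751 points) for CstF-64 siRNA, 182 and 192 between controls, and 427 and 77 (median 2.23 points) in the direct comparison. A minimum of 20 points gave 491 and 26 loci for CF Im 68 siRNA, 110 and 49 for CstF-64 siRNA, 129 and 115 between controls, and 537 and 59 in the direct comparison. The last of these counts are lower by construction. The settings with at least 200 reads and without the most read positions tested fewer loci than the 4793 of the main setting, which also lowers counts. Causes beyond this were not tested, and without the most read positions the medians fell as well.

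Against the no siRNA library alone, CF Im 68 siRNA gave 426 distal loci and a median of 5.23 points. CstF-64 siRNA gave 911 proximal and 642 distal loci and a median change of the mean end distance of −7.32 nt. Against control siRNA alone, CF Im 68 siRNA gave 207 distal loci. The 2 kb window gave 77 distal loci for CF Im 68 siRNA and 150 in the direct comparison. A cluster radius of 10 nt gave medians of 3.63 points for CF Im 68 siRNA and 2.98 points in the direct comparison. The most 5′ and 3′ sites in place of the most used pair gave medians of 5.53 and 4.24 points.

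For locus totals at least 2-fold apart, the no siRNA library alone gave 2303 higher and 1103 lower loci after CF Im 68 siRNA, and 1453 and 2285 after CstF-64 siRNA. A pseudocount of 0.1 RPM gave 709 lower loci after CF Im 68 siRNA, and 525 higher and 1991 lower after CstF-64 siRNA. For CstF-64 siRNA, TMM factors gave 496 higher loci, DESeq2 size factors 500, and leaving out sites of 1 library 210. Mitochondrial shares after CF Im 68 siRNA were 4.01% over sites of at least 1 RPM and 6.62% without the most read positions, and control siRNA had 1.62% and 2.88%.

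No paired analysis was possible because each group held 1 library. Counting distinct alignments, leaving out sites next to A stretches, extending terminal exons, and the planned steps on introns, targeted genes and sequence were not run.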

Other observations

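The test of single-position sites below was chosen after the result was seen.

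Reads within a site were slightly more concentrated on the most read position after either depletion. In 4250 sites with at least 200 reads in every library, each thinned to 200 reads, the most read position held a mean of 66.6% of the reads without siRNA, 66.9% after control siRNA, 69.1% after CstF-64 siRNA and 68.6% after CF Im 68 siRNA. The share was above that of control siRNA at 62.3% of sites after CstF-64 siRNA and below it at 33.0%. After CF Im 68 siRNA it was above at 59.2% and below at 36.4%. Without siRNA it was above at 45.01% and below at 50.2%. The mean number of positions used per 200 reads was 8.30 without siRNA, 8.22 after control siRNA, 7.65 after CstF-64 siRNA and 7.95 after CF Im 68 siRNA. Copies of amplified fragments would also raise the share of the most read position and lower the number of positions. Thinning to 200 reads does not remove such copies. Sites read in practice in a single library, counted below, were more numerous after either depletion than in the controls. Their share of the library's reads was not higher than after control siRNA. It was 0.141% without siRNA, 0.437% after control siRNA, 0.434% after CstF-64 siRNA and 0.366% after CF Im 68 siRNA. These values cannot separate a change in cleavage from amplification, and neither was tested here.

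Most mitochondrial reads lay at 4 sites of chromosome M. The site at position 225 on the minus strand had 3346 RPM without siRNA, 4206 RPM after control siRNA, 5809 RPM after CstF-64 siRNA and 15167 RPM after CF Im 68 siRNA. The ratio of CF Im 68 to control siRNA was 3.61 there (3.57 to 3.64), 3.42 at position 376 on the minus strand, 3.43 at 5513 on the plus strand and 2.12 at 12139 on the plus strand. After CstF-64 siRNA these 4 sites together were at 1.41 times control siRNA (1.40 to 1.42) and 1.85 times no siRNA, while reads outside them were at 0.631 and 0.935 times on the plus strand and 0.688 and 0.804 times on the minus strand, in the same order. At 11806 on the plus strand, CF Im 68 siRNA gave 102.3 RPM, against 202 RPM after control siRNA and 118 RPM without siRNA. Of the 16 largest mitochondrial sites, 8 were over 2-fold higher after CF Im 68 siRNA than in both controls. Reads of nuclear sites below 1 RPM made up 4.68% of nuclear reads without siRNA, 6.21% after control siRNA, 5.27% after CstF-64 siRNA and 6.93% after CF Im 68 siRNA.

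Some sites were read in practice in 1 library alone. There were 622 sites with at least 99% of their reads in 1 library: 78 without siRNA, 154 with control siRNA, 189 with CstF-64 siRNA and 201 with CF Im 68 siRNA. Of these, 604 (97.1%) were a single position, against 4.27% of other sites matched on read number, a rate 22.8 times as high. A candidate explanation is the amplification of single fragments, since cleavage at a used poly(A) site spreads over several positions. A biological explanation was not tested for these sites. They took part in 10 of the tested pairs.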
